A study of Mus musculus with 10 samples.

How the data were processed

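Gene expression was measured in single fibres dissociated from the flexor digitorum brevis (FDB), a fast muscle of the mouse foot, after 3 days in culture. The fibres were treated with KN93, an inhibitor of the calcium/calmodulin-dependent kinase (CaMK) pathway, or with KN92, its inactive structural analogue, and were either left unstimulated or given slow-type electrical stimulation. The doses are not given in the sources used here. Per the labels, amplified RNA of the fibres was labelled with Cy3 and a reference sample with Cy5 on each of the 10 arrays, so the dyes were not swapped. The series design describes independent experiments, and its replicates are described there as biological. Here 2 arrays each of unstimulated KN92 (experiments 2 and 3) and unstimulated KN93 (experiments 1 and 3) and 3 arrays each of stimulated KN92 and stimulated KN93 (experiments 1, 2 and 3) were analysed.

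The authors deposited 20 scanner output files, 1 per dye and array, which hold spot and local background intensity on a linear scale. Per the file headers, version 5.5 of the image software was used with automatic segmentation, a background buffer of 3 and a background width of 5; the name of the software is not given in the sources used here. The authors also deposited a table of processed values, a linear ratio per spot. The log2 of this ratio was set against the log2 of Cy3 over Cy5 from the scanner intensities of the same array. Pearson's r was 0.71 to 0.999 across the matched features of an array. The columns of the table have median ratios from 0.91 to 1.20. The features were matched to the table by how closely their Cy3 over Cy5 ratios followed it. The comparison therefore cannot test the direction of the table, which was taken to be Cy3 over Cy5. The normalization and centring of the table stay unknown.

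Each array is 1 grid of 9 rows and 16 columns, which makes 144 spots, and the labels state that each gene has 6 spots. The column for gene identifiers is blank for every spot in all 20 files and no spot carries a flag. The layout was therefore worked out from the values after they were seen: 24 positions of 6 spots, each made of 2 runs of 3 spots, were set against the 22 blocks of 6 rows in the authors' table. Of these positions, 14 were matched to a block, with r of 0.73 to 0.99 over the arrays, and are called here by the number of that block (feature 1, feature 4 and so on). The match of feature 12 was the least certain, since a second block lay almost as close. A further 4 positions were not above background in either dye on any array and were left out, 2 were left out because their 2 runs of 3 spots did not vary together, and 4 unmatched positions were kept. In these 4 too few arrays had signal in both runs for that check, so whether their runs belong together was not tested. The matched and the kept positions made 18 features for testing. The files used here do not pair features with genes. The gene lists, fibre-type genes and cell type markers chosen before the data were examined could not be matched to any feature, so no gene list was tested, no housekeeping gene could be used for centring, and no other cell type could be looked for. The rule for named genes was to take the smallest p-values where fewer than 10 pass in a KN93 against KN92 comparison, or fewer than 6 in the other comparisons. With no gene names it was reduced, per comparison, to the 2 features with the smallest p-values on each side among matched features above background.

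Background was corrected with normexp and an offset of 50, and each array was normalized by loess over the spots of the 18 features, with all other spots at weight 0, in limma 3.58.1 under R 4.3.3. The 6 log2 ratios of a feature, Cy3 sample over Cy5 reference, were averaged to 1 value per array. A linear model of the 4 group means was fitted to all 10 arrays, with 6 residual degrees of freedom, and was tested with limma's moderated two-sided test. P-values were adjusted by Benjamini-Hochberg over the 18 features, and an adjusted p of 0.05 was the threshold. The 5 comparisons were KN93 against KN92 in stimulated and in unstimulated fibres, stimulated against unstimulated fibres with each compound, and the difference between the 2 effects of KN93. Fold changes of comparisons that share no array were correlated across features, with permutation p-values from 100000 draws; features are not independent replicates. The r to be expected with no change was also simulated, after the results were seen, from 2000 sets of arrays with no group difference and the spread of each feature between replicate arrays, under the fit used here and under each block that covers all comparisons.

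The number of arrays limits the precision. Median net signal per array was 1854 to 4940 in Cy3 and 1763 to 6345 in Cy5, over median local backgrounds of 144 to 1076 and 267 to 931. Spots at the ceiling of the scanner were kept, and all 15 in Cy3 and all 27 in Cy5 belong to feature 1. In Cy3 they occurred only on the stimulated KN92 arrays, with 3, 6 and 6 spots in experiments 1, 2 and 3, so they run with 1 of the groups compared; in Cy5 all 6 spots were at the ceiling on each of these arrays, and 2, 4 and 3 on unstimulated KN93 experiments 1 and 3 and stimulated KN93 experiment 1. The folds of feature 1 are therefore not exact. The Cy3 file of stimulated KN93, experiment 3, holds intensities in coarser steps than the other 19 files. Tested on simulated data for stimulated KN93 against KN92, the model recovered 87.4% of features shifted by 1 on the log2 scale, and 49.3% of those shifted by 0.5, with 3 of 18 features shifted. With no shift, 6% of simulations had a call. The normalization itself takes up part of a change on so small an array. When the Cy3 signal of 1 feature was doubled on the stimulated KN93 arrays, a median of 0.73 of a true log2 change of 1 was recovered over 14 features, against 0.90 with median centring. When it was quadrupled, a true log2 change of 2, the lowest value recovered was -0.06, for feature 11, one of the brightest. Fold changes of the brightest features can be understated by this step.

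Of the 45 pairs of arrays, 9 had log2 ratios that correlated below -0.3 across the 18 features, the lowest at -0.52. In 1 of these pairs, stimulated KN92 experiments 1 and 2 at -0.35, both arrays belong to the same group, so the groups cannot oppose each other there. The dyes in the labels were followed on every array, and the comparisons were also computed with the sign of each of these 2 arrays turned. No pair of arrays held more than 10 identical Cy3 spot means. The image folders named in the file headers place the arrays in 5 scanning sessions, 2 of which hold both compounds. By folder, stimulated KN92 experiments 2 and 3 lie in 1 session and stimulated KN93 experiments 2 and 3 in another. For 2 arrays, stimulated KN92 experiment 3 and stimulated KN93 experiment 2, the image name points to another session than the folder. By image name each of the 3 stimulated experiments holds both compounds in 1 session. Which reading is right is not known, and both were used.

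The alternatives chosen before the data were examined were median centring, scaling between arrays, no background correction, plain subtraction, a filter on dim features, the median of the spots, the authors' processed values, array weights, fits of the compared groups alone, each array left out in turn, and the experiment number as a block. Block-wise loess (1 grid), centring on housekeeping genes (no gene names), leaving out flagged spots (none) and both camera tests (no gene names) were not run. The Cy3 channel alone, the image session as a block (by folder and by image name), the arrays of 1 session alone, normexp with no offset, feature 1 left out of the loess and the test, and the turned signs were added after seeing the data.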

Results

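The effect of blocking the CaMK pathway on the expression of a small set of muscle genes was examined in cultured mouse FDB fibres. Fibres treated with KN93 were compared with fibres treated with KN92, the inactive analogue, both under slow-type electrical stimulation and without it. The stimulated groups had 3 arrays each and the unstimulated groups 2 arrays each. Values are log2 ratios of the fibre RNA to a reference RNA on the same array, each the mean of 6 spots, and are given as mean ± SD. Of 18 features measured, 14 could be matched to the numbered blocks of the authors' table, and none could be given a gene name. Among the unmatched ones, 2 had most spots above background in both dyes on 0 arrays, and they are counted in the 18 throughout.

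In stimulated fibres, the question was whether inhibition of the CaMK pathway changes expression while the slow-type stimulus is applied. Feature 8 had a log2 ratio of -0.41 ± 0.35 (SD, n = 3) with KN93 and 0.08 ± 0.25 (SD, n = 3) with KN92. This is a log2 fold of -0.49 (95% interval -0.92 to -0.07; limma, adjusted p = 0.50). Feature 10 was at -0.17 ± 0.06 with KN93 and 0.17 ± 0.16 with KN92, a log2 fold of -0.34 (95% interval -0.78 to 0.09; adjusted p = 0.50). It was the 1 feature of 18 whose arrays did not overlap between the 2 groups, where chance separates 10% of features. On the side of higher values, feature 4 was at 0.07 ± 0.27 with KN93 and -0.64 ± 0.56 with KN92, a log2 fold of 0.70 (95% interval -0.05 to 1.46; adjusted p = 0.50), and feature 12 had a log2 fold of 0.36 (95% interval -0.14 to 0.85; adjusted p = 0.50). In limma's test 0 of 18 features passed the threshold, and 1 had an unadjusted p under 0.05, where 0.9 would by chance. The 95% interval lay within a doubling or a halving (log2 of 1 either way) for 16 of the 18 features. This does not bound the true difference or show that the compounds act alike, because the loess step takes up part of a change. Within experiments 1, 2 and 3, KN93 minus KN92 was -0.10, 0.715 and 1.503 for feature 4, 0.06, -0.485 and -1.05 for feature 8, -0.26, -0.27 and -0.50 for feature 10, and 0.27, 0.88 and -0.08 for feature 12. By image folder only experiment 1 has both compounds in 1 scanning session. A block on session by folder gave the difference of that pair, which turned the sign of features 4 and 8 (-0.10 and 0.06). By image name all 3 experiments have both compounds in 1 session, so that block cannot move the folds, which were 0.70 and -0.49. Under either reading 0 features were past the threshold. Single arrays also moved the folds: feature 8 was at -0.29 without KN93 experiment 3, whose Cy3 file has coarser steps, feature 4 at 0.40 without KN92 experiment 3, and feature 12 at 0.11 without KN92 experiment 2 and 0.23 without KN93 experiment 1, but at 0.53 without KN92 experiment 1 and at 0.65 with plain background subtraction. With median centring in place of loess, features 8 and 10 were at -0.20 and -0.155, while feature 4 rose to 1.02. The authors' values put features 4 and 8 at 1.04 and -0.72 (limma, both adjusted p = 0.144). Feature 4 ranged from 0.40 to 0.95 and feature 8 from -0.64 to -0.29 when single arrays were left out. In the Cy3 channel alone features 8 and 10 were at -0.02 and 0.18. Their standard errors were 0.44 there, against 0.19 in the ratios, so the Cy3 channel does not settle their signs. With the sign of KN92 experiment 2 turned, features 4 and 12 were at 0.36 and -0.09; with that of KN92 experiment 1 turned, feature 8 was at -0.63 (adjusted p = 0.0552) and feature 12 at 0.47 (adjusted p = 0.258). Over all alternatives the smallest adjusted p of this comparison ranged from 0.0552 to 0.943, and 0 to 4 features had an unadjusted p under 0.05.

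**Figure D1:**
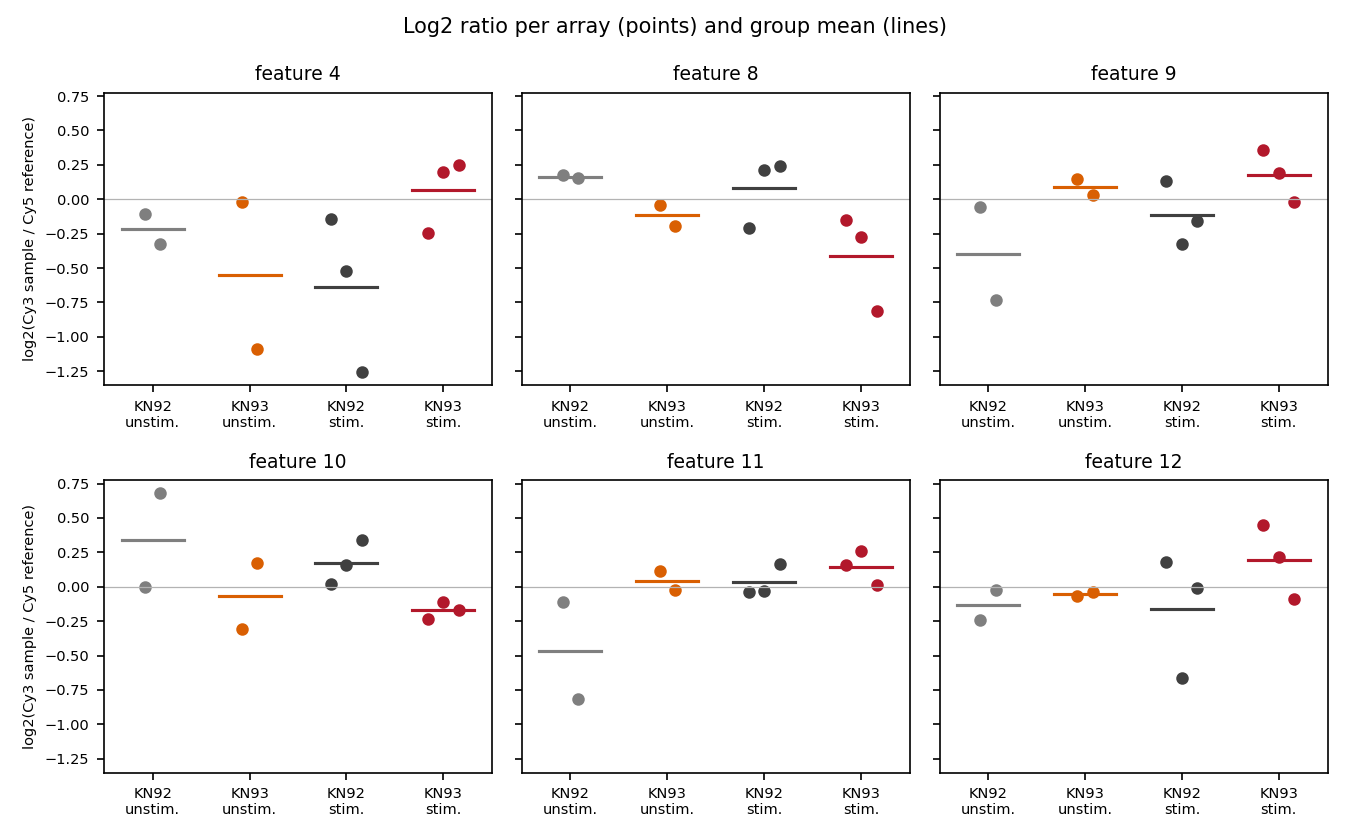
Log2 ratio of fibre RNA (Cy3) to reference RNA (Cy5) for 6 features, vertical axis, in the 4 groups, horizontal axis; each point is 1 array and each line the group mean. The 3 stimulated KN93 arrays of feature 10 all lie below the 3 stimulated KN92 arrays, while in feature 4 the arrays of stimulated KN92 range from -1.25 to -0.15.

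In unstimulated fibres, the same comparison asked whether the inhibitor acts without the stimulus. Feature 11 was at 0.04 ± 0.10 (SD, n = 2) with KN93 and -0.46 ± 0.50 (SD, n = 2) with KN92, a log2 fold of 0.51 (95% interval 0.03 to 0.99; limma, adjusted p = 0.53). Feature 9 was at 0.09 ± 0.09 with KN93 and -0.40 ± 0.48 with KN92, a log2 fold of 0.49 (95% interval -0.05 to 1.02; adjusted p = 0.53). Feature 1 had a log2 fold of -0.21 (95% interval -0.47 to 0.04) and feature 10 one of -0.41 (95% interval -0.94 to 0.12), both with an adjusted p of 0.53. Again 0 of 18 features passed the threshold in limma's test, 1 had an unadjusted p under 0.05, and the 95% interval lay within a doubling or a halving for 15 features. The arrays of 9 of the 18 features did not overlap between the 2 groups, where chance separates 33.3% of features. The count past the threshold and the folds of features 11, 9 and 10 depended on the 2 KN92 arrays, which stood apart on these features. Across the 18 features r was 0.24 between the 2 KN92 arrays and 0.12 between the 2 KN93 arrays, so the KN93 arrays were no closer. Without KN92 experiment 2, 3 features passed: feature 11 at 0.86 (adjusted p = 0.0142), feature 9 at 0.82 (adjusted p = 0.049) and feature 10 at -0.75 (adjusted p = 0.0495), with a lone KN92 array assumed to vary like the other groups. Without KN92 experiment 3, 0 passed, and the same 3 features were at 0.16, 0.15 and -0.07, with a smallest adjusted p of 0.841. With scanning session by folder as a block, features 11, 9, 14 and 4 had log2 folds of 0.79, 0.76, 0.70 and -0.77. These values are the difference of the single pair in a shared session (experiment 3), where features 1 and 10 differed by -0.20 and -0.51. They rest on 1 array against 1, and the error of that fit comes only from stimulated arrays. Its p-values therefore do not measure the spread of the unstimulated arrays. With the session by image name the folds of features 11 and 9 were the same, from the same pair of arrays. With median centring feature 1 was at -0.58, and with the authors' values at -0.52; feature 11 was at 0.30 with median centring. Without KN93 experiment 1 or 3 feature 10 was at -0.17 or -0.65. Feature 1 had 2 and 4 Cy5 spots at the scanner ceiling on the 2 KN93 arrays and 0 on the KN92 arrays, so its fold is not exact. With feature 1 left out of the loess and the test, feature 11 fell to 0.12 (adjusted p = 0.624). Features 14 and 4 are named here after their values were seen. Over all alternatives the smallest adjusted p of this comparison ranged from 0.0142 to 0.841. In the Cy3 channel alone features 11, 9, 1 and 10 had log2 folds of -0.28, 0.15, -0.86 and -0.89, each with a standard error of 0.54. In the ratios the standard errors were 0.21, 0.24, 0.11 and 0.23. The Cy3 folds are therefore less precise and do not settle the signs.

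**Figure D2:**
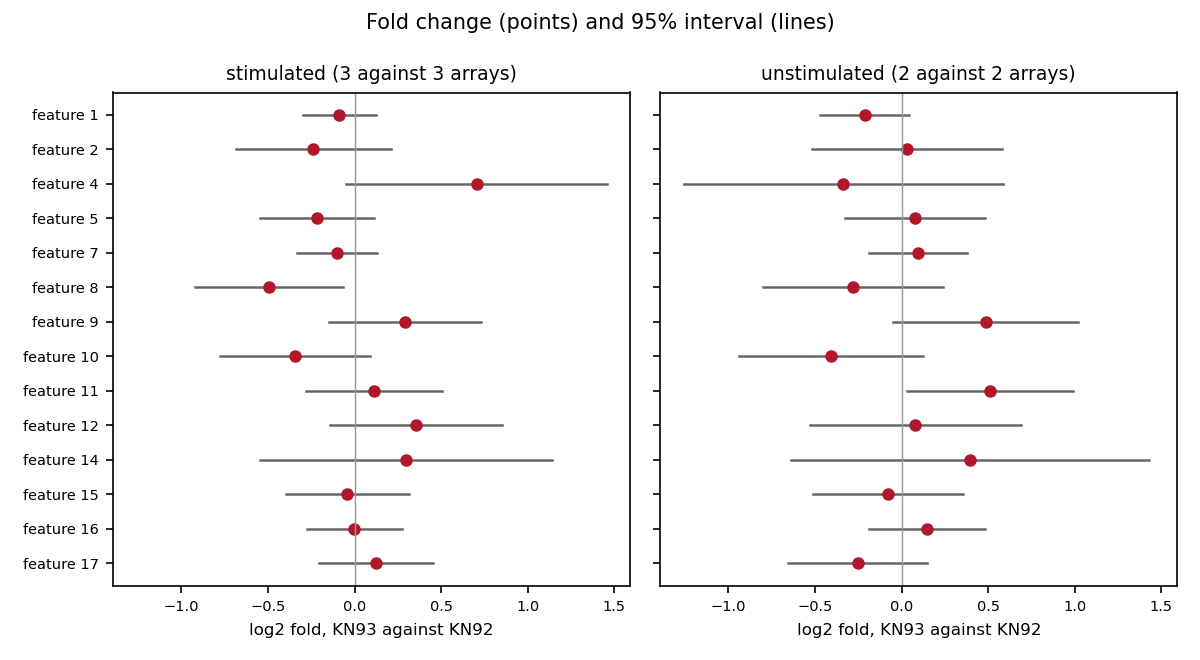
Log2 fold of KN93 against KN92, horizontal axis, for the 14 matched features, vertical axis, in stimulated fibres (left) and unstimulated fibres (right); points are estimates and lines their 95% intervals. The intervals that exclude 0 are those of feature 8 in stimulated fibres (-0.92 to -0.07) and feature 11 in unstimulated fibres (0.03 to 0.99), and neither passed after adjustment.

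The effect of stimulation was compared within each compound, although the stimulated and unstimulated arrays were titled as separate sets of experiments. With KN92, feature 11 had a log2 fold of 0.50 in stimulated against unstimulated fibres (95% interval 0.06 to 0.93; limma, adjusted p = 0.55), and feature 7 one of 0.22 (95% interval -0.04 to 0.48; adjusted p = 0.61). Features 1 and 15 had log2 folds of -0.18 and -0.23, at adjusted p-values of 0.61. That of feature 1 is not exact, since 15 of its 18 Cy3 spots and all 18 Cy5 spots on the stimulated KN92 arrays were at the scanner ceiling. Feature 15 was at -0.105 without unstimulated KN92 experiment 3, at -0.36 without experiment 2, at -0.12 without stimulated KN92 experiment 1 and at -0.001 with the sign of that array turned. Over the alternatives that keep all arrays it ranged from -0.74 to 0.095, and feature 7 from -0.02 to 0.48. No feature passed (0 of 18; 1 with an unadjusted p under 0.05). Without unstimulated KN92 experiment 2, feature 11 passed at 0.85 (adjusted p = 0.0105), and without experiment 3 it was at 0.15 (adjusted p = 0.914). With session by folder as a block feature 14, named after its value was seen, was at 1.12. This value runs through unstimulated KN93 arrays and rests on single arrays, so it is not a fold within KN92. The block by image name also reaches this comparison through KN93 arrays. With median centring feature 1 was at -0.55 and feature 11 at 0.255, and with feature 1 left out of the loess and the test feature 11 was at 0.16 (adjusted p = 0.642). Over all alternatives the smallest adjusted p ranged from 0.0105 to 0.914. With KN93, feature 4 had a log2 fold of 0.62 (95% interval -0.22 to 1.46), feature 17 of 0.19, feature 5 of -0.25 and feature 16 of -0.20, all at an adjusted p of 0.77; 0 of 18 features passed and 0 had an unadjusted p under 0.05. On the pair of KN93 arrays from a shared session, features 4, 17, 5 and 16 differed by -0.23, -0.01, -0.38 and 0.02. With the authors' processed values feature 16 was at -1.12 (adjusted p = 0.0759; 0.0759 to 0.999 over its alternatives), and leaving out single arrays moved it between -0.40 and 0.007. Feature 4 was at 0.085 without unstimulated KN93 experiment 3 and at 1.15 without experiment 1, at 0.175 with session by image name as a block, and feature 17 at 0.081 without stimulated KN93 experiment 3. Over the alternatives that keep all arrays, feature 17 ranged from -0.006 to 0.49 and feature 5 from -0.46 to -0.24. No session held both stimulated and unstimulated KN92 arrays.

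Whether the effect of KN93 differed between stimulated and unstimulated fibres was tested as an interaction. For feature 4 the log2 fold was 0.70 with stimulation and -0.34 without, a difference of 1.04 (95% interval -0.15 to 2.23; limma, adjusted p = 0.83). Feature 17 differed by 0.38, feature 11 by -0.40 and feature 5 by -0.30, all at an adjusted p of 0.83. The difference of feature 4 was 0.51 without unstimulated KN93 experiment 3 and 1.58 without experiment 1. That of feature 11 was -0.75 without unstimulated KN92 experiment 2 and -0.046 without experiment 3, where that of feature 17 was 0.19, and that of feature 5 was -0.13 without stimulated KN92 experiment 2. Over the alternatives that keep all arrays, the difference ranged from 0.66 to 1.47 for feature 4, from 0.24 to 0.82 for feature 17, from -0.68 to 0.073 for feature 11 and from -0.79 to 0.008 for feature 5. With feature 1 left out of the loess and the test, that of feature 11 was -0.096. In limma's test 0 of 18 features passed and 0 had an unadjusted p under 0.05. Without unstimulated KN92 experiment 2, 0 passed and 3 had an unadjusted p under 0.05, with a smallest adjusted p of 0.101, that of feature 11. Over all alternatives the smallest adjusted p ranged from 0.101 to 0.976.

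Across the 18 features, the log2 folds of stimulation with KN92 and with KN93 had a Pearson's r of 0.03 (permutation p = 0.892, adjusted over 2 correlations 0.892) and a Spearman's rho of 0.13 (permutation p = 0.598, adjusted 0.598). Without the 2 features farthest from the median of the KN92 folds, r was -0.31, and it ranged from -0.43 to 0.32 with arrays left out and from -0.29 to 0.67 over the other alternatives. The folds of KN93 in unstimulated and in stimulated fibres had an r of 0.29 (permutation p = 0.236, adjusted 0.472) and a rho of 0.34 (permutation p = 0.162, adjusted 0.324). On the same side were 12 of 18 features, as many as for the folds of stimulation. Without the 2 farthest features r was 0.19. It was 0.59 with median centring (permutation p = 0.0083), and ranged from -0.052 to 0.52 with arrays left out and from 0.082 to 0.59 over the other alternatives, so whether the 2 effects are related stays open. In simulated arrays with no group difference, 95% of the r of these 2 sets of folds lay between -0.65 and 0.63 under the fit used here. The 2 comparisons in each correlation share no array, and features are not independent replicates.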

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

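All tests of explanations in this part were chosen after the results were seen. A signal appeared at 2 positions that no comparison uses, whose runs of 3 spots did not vary together. Most spots of the position formed by both ends of the first column (column 1, rows 1 to 3 and rows 7 to 9) lay above background in both dyes on 8 of 10 arrays. Most spots of the position that joins the top of column 16 to the middle of column 1 did so on 9 of 10 arrays.

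The level of feature 4 under stimulation was the fold furthest from 0 among the KN93 comparisons, at 0.70 after loess and 0.79 as the difference of the 2 channels, each centred on its median. In the Cy3 channel alone, which holds the fibre RNA, stimulated KN93 minus KN92 was 0.41 (95% interval -0.47 to 1.29). In the Cy5 channel alone, which holds the reference, it was -0.38 (95% interval -1.20 to 0.45). Both intervals include 0, so an effect of KN93 on the fibres and a difference in the reference channel cannot be told apart for this feature. By image folder the scanning sessions of stimulated experiments 2 and 3 each hold 1 compound; by image name each holds both. With the session by folder as a block the fold was -0.10, the difference of the experiment 1 pair alone. By image name it was 0.70 (limma, adjusted p = 0.257), where the block cannot move it because each session with stimulated arrays holds both compounds. Over the alternatives that keep all arrays this fold ranged from -0.10 to 1.04. Its adjusted p ranged from 0.144 to 0.943 over all alternatives. Which reading is right is not known.

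In stimulated KN93 against KN92, 0 features passed the threshold with the real grouping of the 6 arrays, and the highest of the other splits also gave 0. That 10 of the 10 splits gave as many was fixed in advance, because no split can give fewer than 0. At an unadjusted p under 0.05 the real grouping gave 1 feature and the highest of the other splits 3. Of the 10 splits, the real one included, 6 gave at least 1. With 10 splits no share under 0.05 can be reached.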

How the results depend on the processing

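The 2 turned signs, the Cy3 channel alone, the 2 session blocks, the single sessions, normexp with no offset and feature 1 left out were chosen after the data were seen. The counts of features past the threshold stayed at 0 in 133 of 137 recomputations. The exceptions were the session block by folder, with 4 features for unstimulated KN93 against KN92 and 1 for stimulation with KN92, and leaving out arrays, where these counts ranged from 0 to 3 and from 0 to 1; both highest came without unstimulated KN92 experiment 2. This block estimates the error from 2 pairs of arrays; the block by image name gave 0 in all 5 comparisons. The causes were not tested. For the correlation of the stimulation folds (0.03), r was -0.18 with no background correction, -0.16 with plain subtraction, -0.24 with the replicate block shared by both sets, -0.29 in the Cy3 channel alone, -0.20 and 0.54 with the sign of stimulated KN92 experiment 1 or 2 turned, 0.67 with the session block by folder, and -0.43 to 0.32 with arrays left out. Under the 2 session blocks both effects use unstimulated KN93 experiment 1. Arrays simulated with no change gave a median r of 0.38 by folder (95% range -0.30 to 0.81) and 0.56 by image name (-0.09 to 0.88), which hold the observed 0.67 and 0.36. The other causes were not tested. The correlation of the 2 KN93 effects was 0.59 with median centring, 0.53 with the authors' values, 0.52 and 0.15 with the session block by folder and by image name, and -0.052 to 0.52 with arrays left out.

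The sign of named features turned in 20 of 558 recomputations, 5 of them single sessions that repeat the block by folder. Many cannot turn a sign (arrays outside the comparison left out), so this does not show stability. With plain subtraction, feature 16 was at 0.23 (stimulation, KN93), and with the authors' values feature 15 was at 0.095 (stimulation, KN92). In the Cy3 channel, feature 10 was at 0.18 (KN93, stimulated), and feature 11 at -0.28 (KN93, unstimulated), -0.03 (stimulation, KN92) and 0.073 (interaction). The standard errors of these 4 values were 0.44, 0.54, 0.50 and 0.70, so the turned signs are not settled. With the session block by folder, features 4 and 8 were at -0.10 and 0.056 (KN93, stimulated), and features 4, 17 and 16 at -0.23, -0.006 and 0.017 (stimulation, KN93). With experiment 2 of stimulated KN92 turned, features 12, 7 and 5 were at -0.086, -0.02 and 0.008. With arrays left out, feature 16 ranged from -0.40 to 0.007 (stimulation, KN93). Without feature 1, feature 11 was at 0.12 (KN93, unstimulated) and 0.16 (stimulation, KN92).

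Whether the experiment numbers pair the stimulated arrays could not be settled. Same-numbered arrays deviated from their group means with correlations of 0.13, -0.13 and -0.41. Only KN92 experiment 1 correlated best with the array of its own number. The deviations of a group sum to 0 over so few arrays that these correlations cannot show that a pairing is absent. The replicate block within each set left 0 features past threshold in the 2 KN93 comparisons and the interaction, and the block shared by both sets left 0 in all 5. Plain subtraction kept 15 features, the filter on dim features 16 and the authors' values 14. The 2 features that filter removes had median net signals below 0 in both dyes, so their ratios carry little signal.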

Other observations

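The tests of explanations in this part were all chosen after the values were seen. For 14 of 18 features, the SD between replicate arrays was above the median SD of the 6 spots on an array. The other 4 were feature 1 and 3 unmatched positions. An array value is a mean of 6 spots, so spot noise alone would make it spread less than single spots do. These 4 features therefore do not show that their arrays differed no more than spot noise. For feature 14 the median SD of the 6 spots was 0.058 on the log2 scale and the SD between replicate arrays 0.58, a ratio of 10.0. For feature 4 the ratio was 8.41. In feature 1, whose spots reach the scanner ceiling, the 2 SDs were 0.070 and 0.063. Without names of the genes, no biology of these features can be described.

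The reference channel was not level between arrays. After centring each array on its median, the Cy5 level of a feature ranged over a median of 3-fold across the 10 arrays, from 1.61-fold to 6.37-fold. The highest belongs to an unmatched position with a median net Cy5 signal of -165.2, below background, so that fold is not a reliable level of the reference. Among matched features the highest was 4.52-fold, for feature 12. The hypothesis that this follows the scanning session was tested by permuting the arrays over sessions. With the session read from the image folder, 14 of 18 features had an adjusted permutation p under 0.05. These include a position with a median net signal below background and feature 1, whose Cy5 spots reach the scanner ceiling. Read from the image name, 8 had an unadjusted p under 0.05 and 0 an adjusted one. The hypothesis therefore stays open, since which reading is right is not known. The other explanation was the group of fibres on the array, and the level spread more within a fibre group than within a session for 18 of 18 features by folder and 17 by image name, which argues against the group as the whole cause. Whether the reference RNA, its labelling or the scan differed between sessions was not tested. Nor is the range particular to the reference, since the Cy3 level moved too. For feature 11 the centred log2 levels in Cy3 and Cy5 were 4.03 and 4.00 on stimulated KN92 experiment 1. On stimulated KN93 experiment 3 they were 2.33 and 2.37. Feature 4 was at -0.03 and 0.81 on stimulated KN92 experiment 3 but 0.99 and 0.28 on stimulated KN93 experiment 2. How much both dyes share, which cancels in the ratio, was not tested. In the log2 ratios the permutation over folder sessions gave 1 feature with an unadjusted p under 0.05 and 0 after adjustment.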
